A study of Mus musculus with 2 samples.

How the data were processed

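Trimethylation of lysine 9 on histone H3 (H3K9me3), a mark of silent heterochromatin, was mapped by chromatin immunoprecipitation and sequencing in the forebrain of C57BL/6 mouse embryos (strain B6NCrl) at 16.5 days of gestation. There was 1 group with 2 biological replicates, each a pool of male and female embryos per the labels. Replicate 1 had 1 technical library. Replicate 2 had 2 technical libraries, from a pool of 41 embryos. The labels describe no second tissue, age or treatment, so no groups were compared. The questions that the design allows are how far the replicates overlap and where in the genome the peaks lie.

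The deposited files used here were 4 peak lists in narrowPeak format on the mm10 assembly. Per the file headers and listings that accompany them, the authors called peaks on each replicate separately and on both replicates together (the pooled list), and then derived a replicated list from these 3 lists. The aligner, the peak caller, its thresholds and the rule behind the replicated list are not given in the sources used here. The fold enrichment of each peak is the authors' deposited ratio over background, on a linear scale. The −log10 p-value and −log10 q-value of each peak were also taken as the authors deposited them. The smallest deposited −log10 p was 2.01 in replicate 1 and 2.03 in replicate 2. Fold enrichment was used only to describe, rank, filter or compare peaks within a list, because it belongs to the peak and not to a comparison of libraries. The per-replicate lists were read as derived from different sets of input files, a pair beyond the alignments for replicate 1 and a single one for replicate 2, per the labels' listings. Such a difference can change the background against which peaks are called. The peak lists hold no read counts, so the sequencing depth is unknown and no interval for depth can be given.

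Peaks were placed on the GRCm38.p6 reference, the same build as mm10. The lengths of all 21 chromosomes were compared with the peak positions, and no peak ran past a chromosome end. Genes, exons and coding sequence came from GENCODE mouse release M21. Soft-masked sequence came from the reference and carries no repeat class. Peaks on sequences not placed on chromosomes 1 to 19, X and Y were left out of all tests of position and are described in the closing section.

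Peak sets were compared with rotations, in which all peaks of a list were shifted along each chromosome by 1 random offset with the ends wrapped. A rotation keeps the spacing of neighbouring peaks and the clustering of gene families, which a test over single peaks would ignore. Peaks overlapped when they shared at least 1 bp. The replicate overlap and the Jaccard index of covered bases used 1000 rotations. Peak bases were divided, in this order, into promoters (1 kb on either side of a transcription start), exons, introns and intergenic sequence, again with 1000 rotations. The number of protein-coding genes of each of 20 lists whose gene body overlapped a replicated peak was tested with 10000 rotations. The soft-masked and GC share of peak bases was tested with 200 rotations. All of these were two-sided permutation tests. Those of features and gene lists were adjusted by the Benjamini-Hochberg method over the features or over the 20 lists. The tests of replicate overlap and of sequence content were not adjusted. Chromosomes were tested with two-sided exact binomial tests against their share of assembled sequence, adjusted in the same way over the chromosomes. Neighbouring peaks are not independent, so these binomial p-values are too small. The position of peaks along zinc finger genes was tested with a two-sided exact binomial test against 0.5 over genes. Intervals are exact (Clopper-Pearson) 95% intervals and cover counting error only. Results were called at an adjusted p below 0.05, or at a p below 0.05 where no adjustment was made.

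The gene lists, the main tests and all but 2 of the alternatives were fixed before the data were examined. Tests and comparisons added later are named as such where they are reported. The lists cover C2H2 zinc finger, clustered protocadherin, olfactory receptor, vomeronasal receptor, imprinted, germ cell, Hox, forebrain transcription factor, long neuronal, cytochrome P450 and conjugating enzyme, secreted or skin protein, histone, and X and Y multicopy genes. Further lists hold housekeeping genes and markers of neurons, radial glia, red blood cells, endothelium, microglia and other organs. Members were chosen by symbol, so a list can hold relatives that share only a name. The genes named in the text were chosen by a rule. It took up to 3 genes per list with the most bases in replicated peaks among genes also covered in both replicates, the 10 protein-coding genes with the most covered bases, the 10 replicated peaks with the highest fold with the gene each overlaps, and every covered imprinted gene. All covered members of some short lists are also named, and genes picked after their values were seen are stated to be so. Tied fold values were ordered by −log10 p and then at random with a fixed seed. This order replaced one by position after a first table was seen.

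The alternatives were the pooled list, each replicate alone, peaks at a deposited q of 0.01 or lower, peaks at or above the median fold of their list, overlap of at least 50% of 1 or of both peaks, peaks within 1000 bp joined, autosomes only, covered bases per Mb, peak midpoints, gene bodies extended by 5 kb, 2 kb around the transcription start, at least 500 bp covered, and random genes of matched length in place of rotation. Replicated peaks that overlap the lists of both replicates, and rotation without assembly gaps, were added after the data were seen.

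The tests of the main results were run on simulated data, that of the chromosomes only after its result was seen. The tests of the closing section were not. A planted list of 200 genes, 120 of which were given a peak, had 134 covered genes against a rotation mean of 23.0 over 21938 protein-coding genes. The gene list check used the real peaks after rotation as its background. On that background, 2 of 100 unrelated lists of clustered genes had a p of 0.05 or lower. Rotated peaks gave no feature with an adjusted p below 0.597. Peaks that are already rotated should rarely differ from further rotations. Both checks therefore test the code, and do not show that rotation is a fair background for the real peaks. Of 200 sets of peaks drawn evenly over the chromosomes, 13 had a chromosome with an adjusted p of 0.05 or lower. These sets lack the clustering of the real peaks. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.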

Results

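H3K9me3 was profiled in 2 pools of mouse embryonic forebrain at 16.5 days of gestation. Replicate 1 had 32822 peaks covering 8.41 Mb and replicate 2 had 19648 peaks covering 5.33 Mb, so replicate 1 had 1.67 times as many peaks. Median peak width was 211 bp in replicate 1 and 221 bp in replicate 2. Median fold enrichment was 3.44 and 3.57, and 25.2% and 11.2% of the peaks had a deposited q of 0.01 or lower. The replicated list held 13716 peaks covering 4.83 Mb, with a median width of 281 bp, a median fold of 3.60 and 42.2% of peaks at a q of 0.01 or lower. Its strongest peak, with a fold of 18.5, covered Klf14. Sequencing depth is unknown, because the peak lists carry no read counts.

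The design asks first how far the replicates overlap. The peaks shared most often were the strongest ones. Each list was ranked by its own fold and cut into 10 equal parts. In the highest part of replicate 2, 71.3% (95% interval 69.2 to 73.3) of peaks overlapped a replicate 1 peak, against 38.1% (35.9 to 40.3) in the lowest part. In replicate 1 the share was 53.5% (51.7 to 55.2) in the highest part and 17.4% (16.1 to 18.8) in the lowest. Over whole lists, 24.8% of replicate 1 peaks and 41.4% of replicate 2 peaks overlapped the other replicate. With at least 50% of both peaks covered the shares were 14.5% and 24.4%, and among peaks at a q of 0.01 or lower they were 13.4% and 50.8%. That filter, applied to both lists, left 8274 peaks in replicate 1 and 2194 in replicate 2. A shorter list limits the share of the longer list that can overlap it. The 13.4% therefore does not show that stricter peaks of replicate 1 were shared less. For the whole lists rotation gave 0.434% ± 0.080 and 0.727% ± 0.134 (SD, n = 1000 rotations), and the two-sided permutation p of 0.002 was the smallest that 1000 rotations can give. The Jaccard index of covered bases was 15.8%, against 0.142% after rotation (permutation p = 0.002). The deposited fold took only 769 distinct values in replicate 2 and 972 in replicate 1, so many peaks are tied. In replicate 2 the shares did not fall smoothly, with 27.2%, 39.5% and 28.0% in parts 7, 8 and 9. Whether the ties account for this was not tested.

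**Figure D1:**
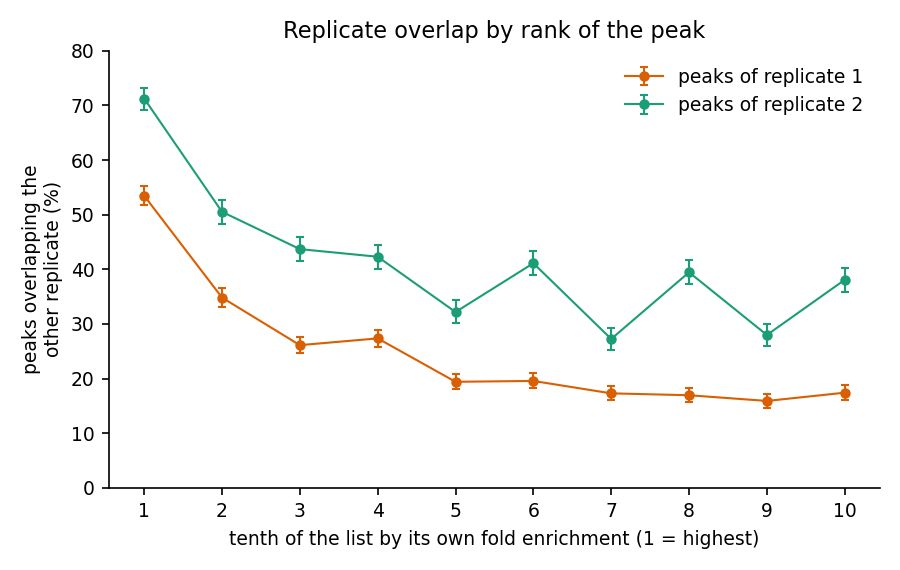
Share of peaks (%, y axis) that overlap a peak of the other replicate, in 10 equal parts of the list ranked by its own fold enrichment (x axis, 1 = highest), for replicate 1 and replicate 2; bars are exact 95% binomial intervals for counting error. The highest part overlaps most often in both lists, at 53.5% in replicate 1 and 71.3% in replicate 2.

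The pooled list shows which peaks the authors kept as replicated. Of 21199 pooled peaks, 64.7% (64.1 to 65.3) were in the replicated list. A peak of replicate 1 overlapped 70.6% of pooled peaks and a peak of replicate 2 overlapped 57%. Both replicates overlapped 36.7% and neither overlapped 8.98%. Within the replicated list, 7601 peaks (55.4%) overlapped a peak of both replicates, 3522 overlapped replicate 1 alone, 2089 overlapped replicate 2 alone and 504 overlapped neither. Median fold was 3.89 in the peaks with both partners and 3.14 in those with neither. Replicated peaks with both partners were therefore also tested on their own wherever a gene list is reported.

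The mark was unevenly spread over the chromosomes. Chromosome 7 had 1764 replicated peaks, or 12.4 per Mb. That was 2.45 times its share of assembled sequence (adjusted p = 1.42e-252, exact binomial test), with ratios of 2.15 in replicate 1 and 2.32 in replicate 2. Chromosomes 17, 4 and 18 followed with ratios of 1.72, 1.55 and 1.45. Chromosome X had 188 peaks and a ratio of 0.226 (adjusted p = 6.26e-166, exact binomial test). Its ratio was 0.271 in replicate 1 and 0.557 in replicate 2, with an SD of 0.202 (n = 2) against 0.120 for chromosome 7. Chromosome Y had 3 peaks, where 96.3% of the assembled sequence is soft-masked. That share is 46.8% on chromosome X, against 30.6% to 35.8% on the autosomes. The ratios allow neither for soft-masked sequence nor for the copy number of X and Y in pools of both sexes. Low ratios there thus need not mean that the mark is scarce. In all, 8 chromosomes were above and 10 below their share, out of 21. The calls for chromosomes 9, 11 and 12 were each lost under at least 1 alternative. Of the 21, 18 lay on the same side of 1 in the replicated list and in both replicates. Chromosome 19 lay below 1 in the replicated list (0.939, adjusted p = 0.319, exact binomial test) and above 1 in replicate 1 (1.01) and replicate 2 (1.12, where it passed).

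**Figure D2:**
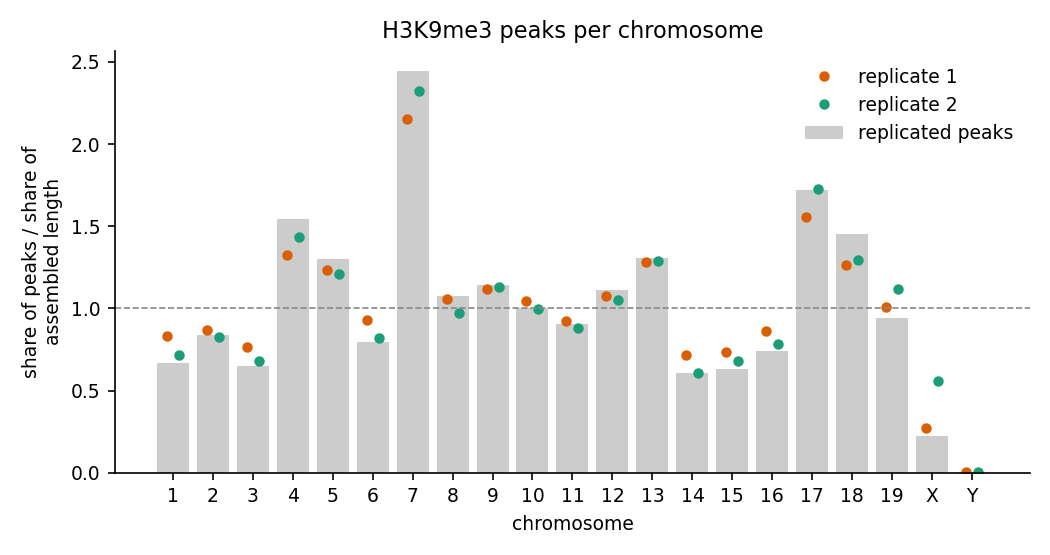
Share of peaks on each chromosome (x axis) divided by its share of assembled sequence (y axis, no unit); bars are the replicated peaks, points are replicate 1 and replicate 2, and the dashed line marks 1. Chromosome 7 has the tallest bar at 2.45, and chromosome X lies at 0.226 with the replicates at 0.271 and 0.557.

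Peaks lay over exons more than over any other part of genes, relative to rotation. Exons outside promoters held 10.2% of replicated peak bases, against 4.00% after rotation (ratio 2.56, adjusted permutation p = 0.00799), and the ratio was 1.88 in replicate 1 and 2.29 in replicate 2. Much of the covered coding sequence, promoters included, came from a few families. Of 288040 coding bases in replicated peaks, 90290 lay in C2H2 zinc finger genes and 69345 in clustered protocadherins. The exon share was not tested without these lists. Promoters held 5.25%, against 4.00% (ratio 1.31, adjusted permutation p = 0.012). Introns held 35.5%, against 39.9% (ratio 0.890, adjusted permutation p = 0.0133). Intergenic sequence held 49.0%, against 52.1% (ratio 0.941, adjusted permutation p = 0.12). The promoter excess did not hold in either replicate alone (ratios 1.03 and 1.17), and by peak midpoints its ratio was 0.959. It was larger among peaks at a q of 0.01 or lower (ratio 1.76, adjusted permutation p = 0.004), at or above the median fold (1.58, adjusted permutation p = 0.008) and found in both replicates (1.60, adjusted permutation p = 0.004).

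Of the 20 gene lists, 6 were covered by replicated peaks above rotation and none below it (adjusted p, two-sided permutation test). Another 14 did not pass, of which the long neuronal list was at a permutation p of 0.0384 before adjustment. The lists above rotation were the imprinted genes, the clustered protocadherins, the C2H2 zinc finger genes, the germ cell genes, the vomeronasal receptors and the cytochrome P450 and conjugating enzyme families. Over all 21938 protein-coding genes, 2412 (11%) carried a replicated peak, a ratio of 1.00 to rotation (permutation p = 0.971).

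**Figure D3:**
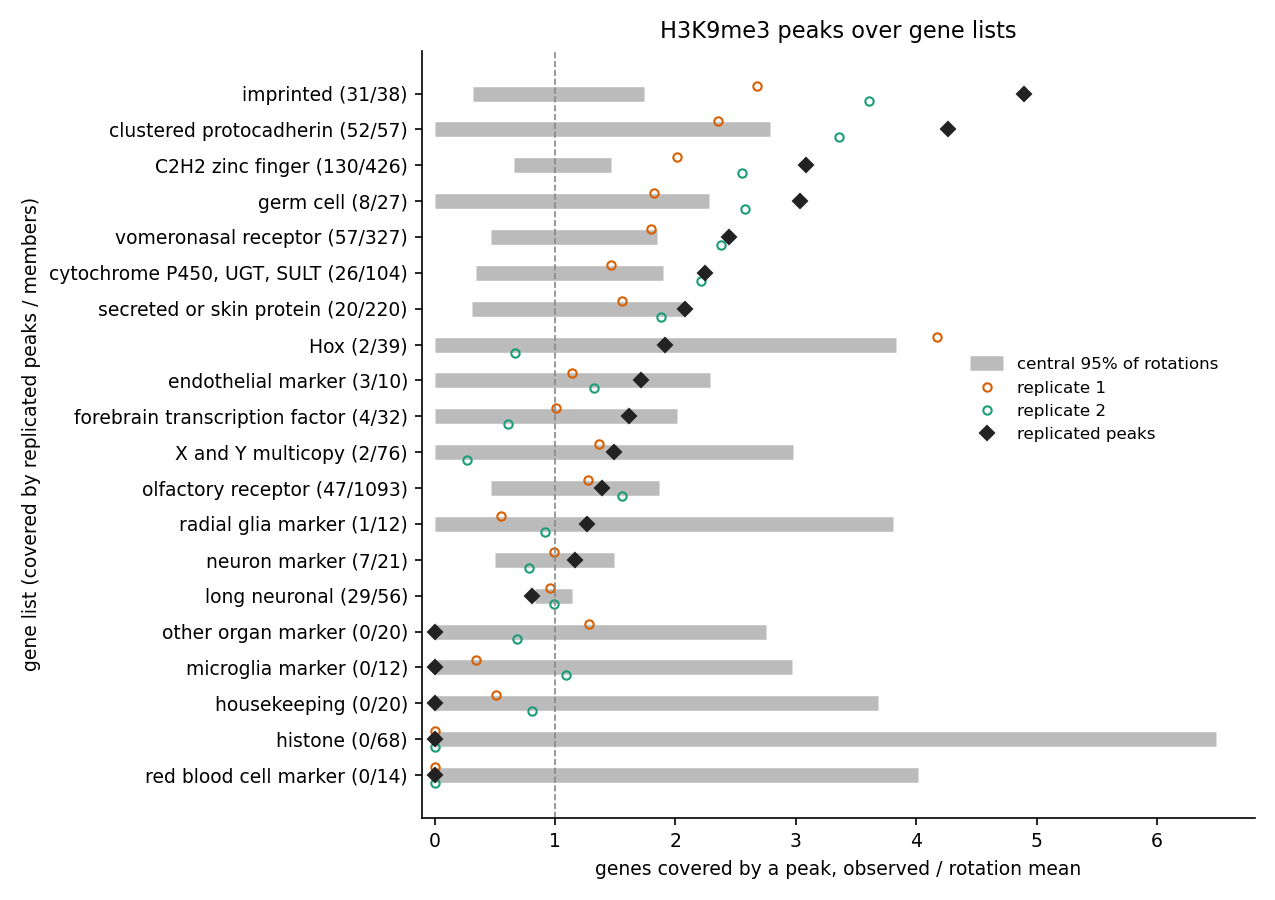
Number of genes of each list covered by a peak, divided by the mean of 10000 rotations (x axis, no unit), for the replicated peaks, replicate 1 and replicate 2; grey bars span the central 95% of rotations of the replicated peaks, and the dashed line marks 1. The y axis gives each list with its covered and total members. Imprinted genes lie at 4.89, clustered protocadherins at 4.27 and zinc finger genes at 3.08, while Hox genes lie at 4.17 in replicate 1 and 0.670 in replicate 2.

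The clustered protocadherins, cell-surface adhesion proteins of which single neurons express different combinations, were covered in long arrays of peaks. Of 57 genes on chromosome 18, 52 were covered, against a rotation mean of 12.2 (ratio 4.27, adjusted permutation p = 0.00133), and 53 were covered in each replicate. Rotation means were higher for the longer lists of the replicates, so the ratio was lower there, 2.35 in replicate 1 and 3.36 in replicate 2. Between positions 36930184 and 37841873 the replicated list had 281 peaks over 160 kb (17.5% of the region), replicate 1 had 397 over 160 kb and replicate 2 had 323 over 145 kb. Peaks covered 50.3% of the coding bases of these genes and 15.4% of their introns. By family, counting coding blocks of at least 1500 bp, 18 of the 21 Pcdhg blocks, 12 of the 14 Pcdha blocks and 20 of the 22 Pcdhb blocks were covered, with 74.6%, 50.3% and 27.6% of their bases in peaks. The shares were 69.2%, 46.0% and 26.1% in replicate 1 and 68.9%, 41.8% and 27.4% in replicate 2. Pcdhga1 (ENSMUSG00000103144, chromosome 18, 37661793 to 37841873, plus strand) had 78772 covered bases in 85 peaks. The replicates had a mean of 72410 ± 1247 bases (SD, n = 2). Its strongest peak, at 37738090 to 37740312 with a fold of 10.1, lay in an intron of it. The same peak overlapped a coding exon of another Pcdhg gene, at 37737120 to 37739543. The gene bodies of Pcdhga1 to Pcdhga5, Pcdhgb1 and Pcdhgb2, and of the read-through models Gm42416, Gm37013 and Gm37388, overlap one another. These 10 genes, the protein-coding genes with the most covered bases, therefore share most of their covered bases.

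**Figure D4:**
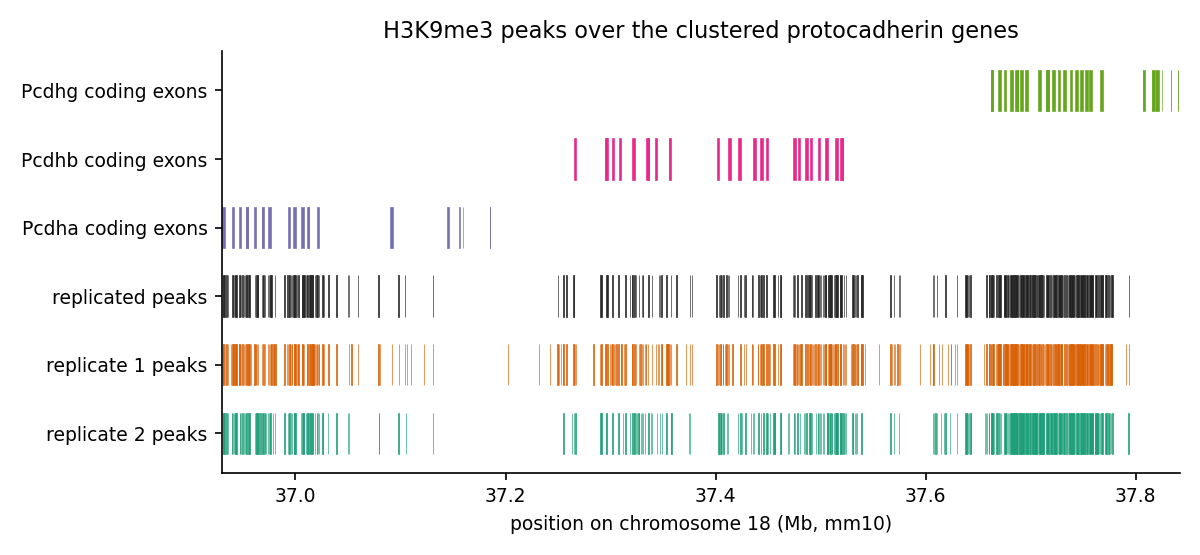
Peaks of the replicated list, replicate 1 and replicate 2 and coding exons of the Pcdha, Pcdhb and Pcdhg genes (y axis, 1 row each) along chromosome 18 in Mb of mm10 (x axis), from 36930184 to 37841873. Peaks lie over the arrays of coding exons in all 3 peak rows and are densest over Pcdhg, where 74.6% of the bases of the long coding blocks are in replicated peaks.

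C2H2 zinc finger genes, a large family that includes the KRAB repressors of transposons, had 130 of 426 members covered, against a rotation mean of 42.2 (ratio 3.08, adjusted permutation p = 0.00133). The ratio was 2.01 in replicate 1 (178 covered), 2.55 in replicate 2 (145) and 4.36 with peaks found in both replicates (114). Here too the rise in ratio came from lower rotation means, as fewer genes were covered. Peaks covered 10.8% of their coding bases and 1.44% of their introns. Zfp2 (ENSMUSG00000049321, chromosome 11, 50898712 to 50916165, minus strand) had 68.0% of its length in 16 peaks, 11867 bases in all, with a replicate mean of 9384 ± 2230 bases (SD, n = 2). Zfp110 (ENSMUSG00000058638, chromosome 7, 12834761 to 12850577) had 10749 bases and Zfp873 (ENSMUSG00000061371, chromosome 10, 82048123 to 82064745) had 10708 bases. The strongest peak of each of these genes overlapped coding exons. Around the transcription start alone (2 kb on either side), the list was not above rotation (ratio 1.49, adjusted permutation p = 0.907).

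Within covered zinc finger genes the mark lay toward the 3′ end, where the exon that encodes the finger array usually sits. More peak bases lay in the 3′ than in the 5′ part of the gene in 103 of 130 genes (79.2%, 95% interval 71.2 to 85.8, p = 1.18e-11, exact binomial test). The share was 70.8% in replicate 1 and 79.3% in replicate 2. Mean coverage was 0.158% of bases in the first twentieth of the gene and 29.0% in the twentieth numbered 19. Neighbouring zinc finger genes are not independent, so the p-value is too small.

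**Figure D5:**
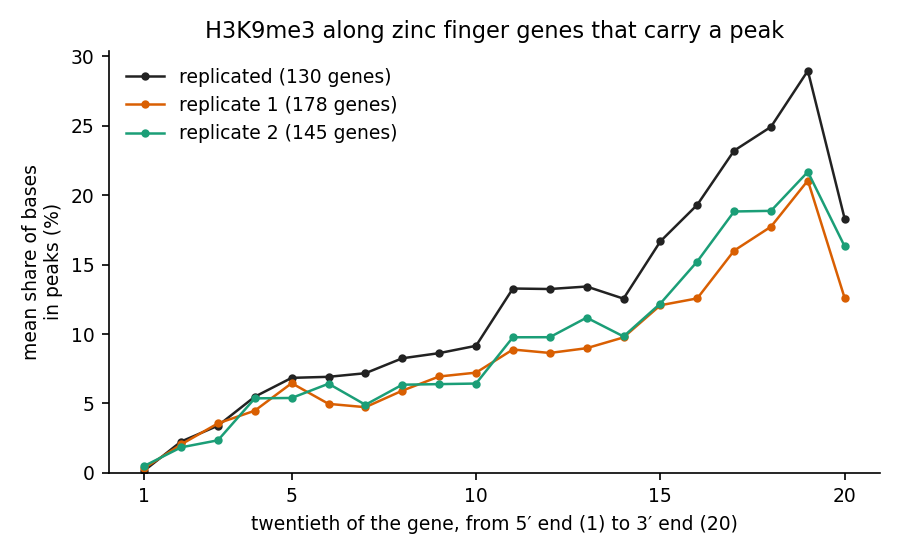
Mean share of bases in peaks (%, y axis) along zinc finger genes that carry a peak, in 20 equal parts from the 5′ end to the 3′ end (x axis), for the replicated list (130 genes), replicate 1 (178 genes) and replicate 2 (145 genes). All lines rise toward the 3′ end, to 29.0%, 21.1% and 21.7% in part 19.

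Imprinted genes, which are expressed from 1 parental allele, had 31 of 38 protein-coding members covered, against a rotation mean of 6.33 (ratio 4.89, adjusted permutation p = 0.00133). The ratio was 2.68 in replicate 1 (33 covered), 3.60 in replicate 2 (30) and 6.59 with peaks found in both replicates (27). The number covered fell as the ratio rose, so the rise came from lower rotation means. Among the 6 members that are not protein-coding, 5 were covered, namely Nespas, Peg13, Airn, Kcnq1ot1 and Meg3. Gnas (ENSMUSG00000027523, chromosome 2, 174284320 to 174346744), which encodes a G protein alpha subunit and several imprinted transcripts, had 6367 covered bases, with a replicate mean of 5295 ± 503 (SD, n = 2). Its strongest peak, at 174284059 to 174285027, overlapped a promoter and the antisense transcript Nespas. Grb10, a growth-restraining adaptor (chromosome 11, 11930508 to 12038683), had 3610 bases, and its strongest peak overlapped a promoter and UTR (replicate mean 4076 ± 1824, SD, n = 2). Trappc9 (chromosome 15) had 3388 bases, and its strongest peak, at 72807807 to 72808798, also lay in an exon of Peg13, the non-coding RNA within it.

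For several imprinted genes the strongest peak overlapped an annotated promoter, which need not be the most upstream one. Peg3, a paternally expressed zinc finger gene (chromosome 7, 6703892 to 6730431), had 1 peak of fold 5.40 at 6728742 to 6730557, over a promoter. The strongest peaks of Impact (fold 6.13), Plagl1 (4.81), Commd1 and Zrsr1 (4.58, a shared peak), Herc3 and Nap1l5 (4.09, a shared peak), Mcts2 (4.57) and Inpp5f (4.77) also overlapped a promoter of the gene. Nnat lies within Blcap, and 65.2% of it was in peaks, while Blcap had 2860 covered bases. Mest had 2695 covered bases, Kcnq1 2649, Kcnq1ot1 1522, Airn 2172, Igf2r 1952, Zfp777 1878, Cdh15 1228, Meg3 1210 and Cdkn1c 1125. Fewer bases were covered in Zfp787 (843), Sgce (654), H13 (616), Ube3a (589), Snrpn (563), Usp29 (488), Zdbf2 (467), Peg10 (373), Mkrn3 (294), Ndn (265) and Magel2 (226). Ndn had no covered base in replicate 2.

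Germ cell genes, which are silent in somatic tissue, had 8 of 27 members covered (ratio 3.03, adjusted permutation p = 0.0224). The strongest peaks of Dazl, Ddx4 and Taf7l, which encode an RNA-binding protein, an RNA helicase and a testis form of a general transcription factor subunit, each overlapped a promoter. The peak of Dazl lay at 50293124 to 50294279 on chromosome 17 with a fold of 5.75, the strongest peak of Ddx4 at 112651700 to 112652058 on chromosome 13 with a fold of 4.86, and that of Taf7l at 134475344 to 134475740 on chromosome X with a fold of 3.95. Within 2 kb of the transcription start the ratio was 12.2 (adjusted permutation p = 0.002). The call was lost in replicate 1 alone (ratio 1.83, adjusted permutation p = 0.113) and with peaks at a q of 0.01 or lower (ratio 3.44, adjusted permutation p = 0.127).

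Vomeronasal receptors, the pheromone receptors of the nose, had 57 of 327 members covered (ratio 2.45, adjusted permutation p = 0.012), with ratios of 1.80 in replicate 1 and 2.38 in replicate 2. Vmn2r60 (chromosome 7, 42107770 to 42196208) had 3388 bases, Vmn2r53 2491 and Vmn2r59 2053, and the strongest peaks of Vmn2r60 and Vmn2r59 lay in introns. The cytochrome P450, glucuronosyltransferase and sulfotransferase families, which process drugs and steroids mainly in liver, had 26 of 104 members covered (ratio 2.25, adjusted permutation p = 0.0393). Ugt1a7c (chromosome 1, 88095062 to 88220002) had 8435 bases in 10 peaks, and Ugt1a10 and Ugt1a5, which share its last exons, had 7636 each. With peaks at a q of 0.01 or lower neither call held, although the ratios were 2.28 for the receptors (adjusted permutation p = 0.112) and 3.03 for the enzymes (adjusted permutation p = 0.068), and the enzyme call was also lost in replicate 1 alone (ratio 1.47, adjusted permutation p = 0.194).

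Olfactory receptors, the largest of the lists, had 47 of 1093 members covered (ratio 1.39, adjusted permutation p = 0.659), and Olfr139, with 1561 covered bases, Olfr398 (1506) and Olfr1349 (753) had the most. Secreted and skin protein families had 20 of 220 covered (ratio 2.08, adjusted permutation p = 0.146). Their most covered members were Skint6, Skint5 and Skint2, of a family of skin T cell selection genes on chromosome 4, with 8721, 5406 and 3418 bases. X and Y multicopy genes had 2 of 76 covered, Rhox13 and Slx4ip, the latter included through its name alone (adjusted permutation p = 0.952). No histone gene of 68 was covered.

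By the number of covered genes, no list of genes that forebrain cells use was called above rotation. Most rotations covered 0 to 5 forebrain transcription factors and 3 to 9 neuron markers, so counts in lists this short can miss an excess. Forebrain transcription factors had 4 of 32 members covered, Cux2, Bcl11b, Cux1 and Tbr1 (ratio 1.61, adjusted permutation p = 0.782), and Bcl11b had a single peak of 1376 bases over a coding exon (chromosome 12, 107915481 to 107916856). Neuron markers had 7 of 21 covered (ratio 1.16, adjusted permutation p = 0.952). Nefm had 1412 covered bases, Nrxn1 had 1243 in 1 peak of fold 7.41 over a promoter and coding exon at 91087712 to 91088954 on chromosome 17, and Syt1 had 810. Long neuronal genes had 29 of 56 covered, against a rotation mean of 35.8 (ratio 0.810, adjusted permutation p = 0.11), with Cdh13 (3590 bases), Magi2 (1616) and Csmd1 (1561) covered most. This list did pass below expectation with peaks found in both replicates (ratio 0.696, adjusted permutation p = 0.0353) and against random genes of matched length (ratio 0.779, adjusted permutation p = 0.024). Radial glia markers had 1 of 12 covered (Aldh1l1) and endothelial markers 3 of 10, among them Flt1 (415 bases) and Tek (212), with adjusted permutation p-values of 1 and 0.802. No housekeeping gene of 20, red blood cell marker of 14, microglia marker of 12 or other organ marker of 20 was covered. Rotation means for these were 0.815, 0.499, 1.35 and 1.09 genes, so that a count of 0 does not set them apart. Replicated peaks held 3.01% of the coding bases of forebrain transcription factors and 3.05% of those of neuron markers. Over all protein-coding genes the share was 0.795%. It was 1.53% and 2.53% for these lists in replicate 1, and 2.16% and 2.69% in replicate 2. For long neuronal genes the replicated share was 0.648% and for radial glia markers it was 0. The shares of coding bases were not tested.

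Hox genes, which pattern the body axis behind the forebrain, differed between the replicates. The replicated list covered 2 of 39, Hoxa3 and Hoxd3 (ratio 1.91, adjusted permutation p = 0.883), with 190 covered bases in Hoxd3. Replicate 1 covered 11 (ratio 4.17, adjusted permutation p = 0.012 over the 20 lists) and replicate 2 covered 1.

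Of the 10 replicated peaks with the highest fold, 5 lay in zinc finger or protocadherin genes and 5 in genes on none of the lists. Klf14 (ENSMUSG00000073209, chromosome 6, 30956023 to 30959078, minus strand), an imprinted single-exon transcription factor gene, was covered over 94.5% of its length by a peak at 30956191 to 30959098. The fold of that peak was 18.5, and the overlapping peaks had folds of 16.2 in replicate 1 and 15.7 in replicate 2. Peaks of fold 10.4 and 9.39 overlapped Gm21887 at the distal end of chromosome X, at 170010991 to 170011426 and 170009104 to 170010038. A peak of fold 10.3 at 180642621 to 180643550 on chromosome 2 overlapped the promoter of Tcfl5, a germ cell transcription factor gene, and another of fold 10.3, at 138604978 to 138607884 on chromosome 5, overlapped coding exons of Zfp68. A further 3 lay in the Pcdhg array, 1 in an intron of the non-coding gene Gm49692 on chromosome 12 (20229995 to 20231859, fold 9.07) and 1 in an intron of Zfp286 on chromosome 11 (62781622 to 62782588, fold 9.05). All 10 overlapped peaks of both replicates.

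Peak sequence was poorer in soft-masked bases and richer in GC than rotated sequence. Soft-masked bases made up 24.0% of replicated peaks, against 33.8% after rotation, and GC made up 46.2%, against 42.1%. The two-sided permutation p of 0.00995 was the smallest that 200 rotations can give. The values were 25% and 45.9% in replicate 1 and 25.6% and 46.0% in replicate 2. Rotated peaks can fall on any assembled sequence, while the peak lists do not show where reads could be placed. The lower soft-masked share therefore does not show that the mark avoids repeats.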

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

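The test of the replicated list's rule was chosen after its result was seen. The predictions for chromosome X and for weak peaks were written before their values. For chromosome X the rules for reading the values were made stricter after both explanations had passed under the first version. The Hox predictions were written after the pattern was seen and before the tested values. Peaks on sequences that are not placed on a chromosome were used in no test of position. The replicated list had 256 such peaks on 19 sequences, 1.87% of its peaks, where no count was set as background. Their median width was 433 bp, against 280 bp for placed peaks, and 84.0% overlapped both replicates, against 54.9% of placed peaks. Wider peaks overlap others more readily, and no rotation was run on these sequences. The higher share therefore does not show that these peaks replicate better. The sequence JH584304 had the most, with 50.

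Chromosome X held 3.44% of the placed peaks of replicate 2 and 1.67% of those of replicate 1, 2.05 times as large a share. A broad difference in X copy number between the pool and its background would add weak peaks evenly. The X share of replicate 2 was 1.38 times as high in the lower as in the upper part of its list by fold (permutation p = 0.0001, the smallest possible), against 0.992 in replicate 1, but the added peaks were not evenly placed. The permutation treated neighbouring peaks as independent, so its p-value is too small. Domains carried by 1 pool would group the peaks, and 36.8% of the 557 X peaks without a partner in replicate 1 lay within 20 kb of another, against 9.16% to 16.7% for even draws. In comparisons added after these values were seen, peaks found in replicate 1 alone grouped as well (33.9%), and without the grouped peaks the X share of replicate 2 was still 2.40%, so the peak lists do not tell the explanations apart, and with 1 group the design names no biological difference to test.

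Part of the replicated peaks had no partner in a replicate's own list. At least 50% of the length was covered in both lists for 45.7% of all replicated peaks, which restates the pattern. By at least 1 bp, 7601 of 13716 replicated peaks overlapped both lists and 504 overlapped neither. Of 7771 pooled peaks that overlapped both lists by at least 1 bp, 170 were left out. Of 6272 with at least 50% of their length covered in both lists, only 2 were left out. These values argue against overlap by 1 bp with both lists as the acceptance rule. Coverage of at least 50% in both lists was nearly always enough for acceptance, but was not required. Which rule was used stays open. The peaks without both partners were also weaker, with a median fold of 3.40 against 3.89 (difference -0.495, permutation p = 0.0001, the smallest possible). Weaker peaks were predicted if they lie near the calling threshold. All 13716 replicated peaks are pooled peaks, however, so their fold rests on both replicates together. Peaks called in each replicate would tend to have a higher fold under any explanation, so the difference does not decide this one. No biological explanation was tested.

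Replicate 1 covered 11 Hox genes and replicate 2 covered 1, and the difference between their ratios to rotation, 3.50 in a test added after the counts were seen, lay outside the central 95% of rotations (-2.68 to 2.27, permutation p = 0.0026). The 15 Hox peaks of replicate 1 lay on all 4 Hox clusters and were mostly weak, at a median percentile of 80.5 from the top of its list, so the greater length of that list may account for part of them. In its top 19019 peaks, close to the number in replicate 2 and also counted afterwards, 7 Hox genes were still covered. Genes of 8 other developmental transcription factor families, such as Pax, Tbx, Lhx, Nkx, Gata, Fox and Irx, were also covered above rotation in replicate 1, 30 of 106 genes or 1.65 times the rotation mean (permutation p = 0.003), and 13 in replicate 2 (ratio 1.10), but that difference between replicates did not pass (permutation p = 0.0738). With 1 pool on each side the comparison is between these libraries only, and the design names no biological difference to test.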

How the results depend on the processing

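Restriction to peaks found in both replicates, and rotation without assembly gaps, were chosen after the data were seen. The clustered protocadherin and imprinted lists, the exon share, the replicate overlap, the 3′ position, the sequence content and the ratios of chromosomes 7 and X kept their direction under every alternative run, and their side of the threshold wherever a p-value was computed. None was computed for covered bases per Mb, where the ratios of chromosomes 7 and X were 2.38 and 0.242. Sizes moved, however. The share of replicate 1 peaks that overlapped ran from 24.9% on autosomes only down to 13.4% at a q of 0.01 or lower. At that q the short list of replicate 2 limits it. The share of replicate 2 ran from 24.4%, with at least 50% of both peaks covered, to 50.8% at that q. The calls for chromosomes 9 (median fold), 11 (q, median fold and both replicates) and 12 (replicate 2 alone, q and both replicates) were lost, and chromosome 8 passed in replicate 1 alone. The protocadherin ratio ran from 2.35 in replicate 1 to 10.2 with at least 500 bp covered and 44.4 around the transcription start, and the imprinted ratio from 2.68 to 9.27 and 15.8 in the same settings. The exon ratio ran from 1.88 by midpoints to 3.44 at a q of 0.01 or lower. The lists above rotation numbered 3, in place of 6, with peaks at a q of 0.01 or lower, with peaks at or above the median fold and with 2 kb around the transcription start (3 each). With a q of 0.01 or lower, ratios that no longer passed were 3.03 for the enzyme families, 3.44 for germ cell genes, 2.28 for vomeronasal receptors and 0.887 for introns. With peaks at or above the median fold they were 2.67, 3.52 and 2.45 for the same lists. Around the transcription start they were 1.27 for the enzymes, 1.96 for the receptors and 1.49 for zinc finger genes. With bodies extended by 5 kb they were 1.91 for the enzymes and 2.37 for germ cell genes, and without assembly gaps 2.15 for the enzymes. Fewer peaks or bases were tested in the stricter sets, and beyond that the cause was not tested. With each replicate alone the ratio ranged from 1.47 to 2.21 for the enzymes, 1.83 to 2.57 for germ cell genes, 1.03 to 1.17 for promoters and 1.01 to 1.12 for chromosome 19, which is above 1 in each replicate and below 1 in the replicated list. The promoter ratio was 1.16 with the pooled list and 0.959 by midpoints, below 1, but 1.76 at a q of 0.01 or lower. Germ cell genes had a ratio of 12.2 around the transcription start. The intergenic ratio passed at 0.843 (q of 0.01 or lower), 0.892 (median fold) and 0.883 (found in both replicates). The share of pooled peaks in the replicated list was 90.1% at a q of 0.01 or lower and 78.5% at or above the median fold. Among the other 14 lists, 149 of the values under alternatives stayed on their side and 5 came to pass. These were long neuronal genes, below expectation, with peaks found in both replicates (0.696) and with random genes of matched length (0.779), secreted and skin proteins with at least 500 bp covered (4.14) and with matched length (2.02), and Hox genes in replicate 1 alone (4.17). Of 76 named genes, 66 were still covered at a q of 0.01 or lower. No paired analysis was possible because there is 1 group. Depth is unknown, so its effect on the lists' lengths could not be measured.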

Other observations

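The test of immunoglobulin heavy chain segments was chosen after its result was seen, and the genes named in this part were picked after their values were seen. Peaks were spread over 2158 of 2737 windows of 1 Mb, with a median of 3 peaks per window that had any. The 15 richest windows held 12.7% of placed replicated peaks and the 50 richest held 27.2%. After the protocadherin window on chromosome 18 (236 peaks) came some windows without genes of the lists and others with zinc finger, vomeronasal receptor or olfactory receptor genes. The window from 144 Mb to 145 Mb on chromosome 4 had 153 peaks, with 210 in replicate 1 and 181 in replicate 2, and held Pramef12, of a family expressed in germ cells, with 3414 covered bases, and the arylacetamide deacetylase relative Aadacl3 with 2914. The window at 61 Mb on chromosome 13 had 116 peaks and held cathepsin genes such as Ctsm. The window at 17 Mb on chromosome 7 had 115 peaks and held Ceacam5 (2284 covered bases) and Ceacam11 (1737), adhesion genes of a family with many placental members. The window at 23 Mb on chromosome 7 had 89 peaks and 18 vomeronasal receptor genes, and Nlrp5, an oocyte gene, had 5804 covered bases there in 19 peaks. The window at 33 Mb on chromosome 7 had 97 peaks among 14 genes of the secreted protein list.

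Immunoglobulin heavy chain variable segments lay in the window at 114 Mb on chromosome 12, which had 138 peaks. Of 113 such segments, 7 were covered, 15.4 times the rotation mean of 0.454 (permutation p = 0.0176), with 14 in replicate 1 and 11 in replicate 2. These segments were picked because their window is rich in peaks, so this value does not test whether they carry the mark. A hypothesis was that antigen receptor segments in general carry the mark in forebrain, and the predicted excess over rotation was not seen. None of 100 kappa segments and none of 136 T cell receptor segments was covered, a ratio of 0 to rotation means of 0.328 and 0.37 (permutation p = 1 for each). Replicate 1 covered 1 kappa and 1 T cell receptor segment, and replicate 2 covered 0 of each. With means this low a count of 0 does not set these segments apart, so the hypothesis was not decided.

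A further hypothesis was that covered gene families merely lie in peak-rich regions. For zinc finger genes the percentage of gene bases covered exceeded that of gene-free sequence within 50 kb by a mean of 2.44 percentage points over 205 gene clusters (higher in 66, lower in 51, permutation p = 5e-05, the smallest possible), and for imprinted genes by 2.80 points over 24 clusters (higher in 21, lower in 2, permutation p = 0.00035). This argues against evenly covered regions, for imprinted genes in 21 of 24 clusters but for zinc finger genes in only 66 of 205. Gene bodies hold exons and gene-free sequence does not, and peaks favoured exons. The comparison therefore cannot say whether the families themselves account for the difference. For vomeronasal receptors the difference was -0.513 points over 47 clusters (lower in 23, higher in 3, permutation p = 0.0006), and for the cytochrome P450 and conjugating enzymes it was -0.251 points over 31 clusters (permutation p = 0.109). Their covered genes may thus reflect peak-rich regions rather than the genes themselves. The protocadherins form 1 cluster, where 25.3% of gene bases and 9.16% of gene-free sequence were covered, a difference of 16.2 points that cannot be tested with a single cluster.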
